A study of Mus musculus with 18 samples.

How the data were processed

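Total RNA from isolated alveolar type II cells was extracted with guanidine thiocyanate, biotin labelled and hybridized by the authors to 18 mouse expression arrays that report 1 value per transcript. The deposited values are on the log2 scale, made by the authors with RMA per the submitters' processing notes, whose version is not given in the sources used here. Which arrays were normalized together, the genome build and any filter are also not given, so no coordinates are reported. The values of the 6 arrays at 0 h had a wider range than those of the 12 arrays at 2 and 24 h, and whether that came from the normalization or the cells was not tested. No values were missing, no 2 arrays were identical, and every column of values was used.

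Samples were grouped by the genotype and the time in their titles into control and Cebpa-deleted cells at 0, 2 and 24 h, with 3 arrays in each of the 6 groups. The sample descriptions state air for every sample, so hyperoxia at 2 and 24 h rests on the series design. The labels record neither batches nor animals. The replicate numbers were checked as possible pairs and did not pair control with Cebpa-deleted arrays.

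Of 35557 features, 21789 had 1 gene symbol, 1621 had several and 12147 had none; 21698 of those with 1 symbol matched the reference table of gene names through their Entrez identifiers. Features with several symbols or none were left out. For the 999 genes with more than 1 feature the one with the highest mean over all arrays was used, which gave 19938 genes, with no filter on low values.

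All comparisons came from 1 linear model per gene with a mean for each of the 6 groups, fitted to the 18 arrays with limma 3.58.1 (lmFit and eBayes with default settings) in R 4.3.3. The contrasts were Cebpa-deleted minus control at each time and averaged over the times, 2 and 24 h minus 0 h within each genotype, and the interactions of genotype with time. Changes from 2 to 24 h within each genotype were added after the data were seen. P-values are two-sided, adjusted over all genes by the Benjamini-Hochberg method, and a gene was called at an adjusted p below 0.05. Standard errors of log2 changes are those of the moderated model.

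Gene lists of pathways, cell states and cell type markers, 31 in number with 563 members of which 522 were measured, were tested with camera at its preset correlation of 0.01, adjusted over the lists of a contrast, and repeated with a correlation estimated for each list and with fry. Members were also counted with p-values adjusted over the list alone. Some genes belong to more than 1 list, but none of the 16 measured endothelial markers does.

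The comparisons, the lists, the first set of other settings below and the rule for named genes were fixed before the data were examined. The rule named Cebpa and its family in every comparison; the 10 largest rises and the 10 largest falls by genotype, or 5 and 5 over time and for interactions, among called genes whose groups did not overlap (for the average, genes with the same sign at every time; for interactions, no such condition); up to 4 called members of each list with the largest change; and, where fewer than 3 genes were called, the 3 of smallest p in each direction. Fewer were printed than the rule allows, in order of rank, and RIKEN and predicted genes were passed over.

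Counts of genes, Cebpa and the named genes were recomputed under other settings, changed 1 at a time: each array left out in turn, a second quantile normalization, arrays centred on their medians, only the arrays of the groups compared, the replicate number as a block, the mean of all features of a gene, every feature tested alone, only the upper 60 percent of genes by mean level (not for Cebpa), eBayes with trend and robust settings, and, for counts alone, a change of at least 1.5-fold. The list tests were recomputed with each array left out, the replicate block, the upper 60 percent of genes, an estimated correlation and fry, and the overlap between times with only the arrays of the groups compared and with an unadjusted p below 0.01. Chosen after the data were seen were the interquartile range of each array as a covariate, leaving out the 2 narrowest Cebpa-deleted 24 h arrays, the average without 24 h, quantile normalization with removal of each array's trend on the mean level, and the list tests under quantile normalization and median centring.

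The fit was tested on simulated data with 19938 genes and 50 changed genes of each size. Of genes changed 1.5-fold it recovered 72% in the 0 h comparison, 72% at 2 h and 78% at 24 h, and of genes changed 2-fold 98%, 100% and 100%, with 12, 9 and 9 false calls. In the simulated lists 1 of 1 raised by 0.5 on the log2 scale was called and 0 of 30 unchanged ones. The simulated noise was independent between genes and had the same spread in all 6 groups. It therefore does not test the calls where genes of a list vary together or where groups differ in spread. Figures were drawn with matplotlib 3.10.9.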

Results

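Gene expression was measured on 18 microarrays of total RNA from alveolar type II cells, the epithelial cells that make lung surfactant, isolated from mice. In the Cebpa-deleted mice the gene for the transcription factor C/EBPα had been removed conditionally from Clara cells early in gestation and from type II cells near birth, and the controls were littermates with the floxed gene but without the rtTA or the Cre transgene. Cells came from mice kept in hyperoxia, a high concentration of inspired oxygen, for 0, 2 or 24 h, which with the genotypes gave 6 groups of 3 arrays. The sample titles give the times and the series design gives hyperoxia, while every sample description states air. The comparisons within a time ask which genes depend on Cebpa in type II cells, and those between times ask which genes change early in hyperoxia. All values are RMA expression on the log2 scale for 19938 genes. The labels do not say that each sample came from a different animal, so the p-values measure the spread between these samples, part of which may be technical, and 3 arrays per group limit the precision.

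The mean of the 21 measured type II cell genes lay between 12.50 and 12.57 on the control arrays at 0 h and between 10.91 and 11.28 on the Cebpa-deleted arrays at 24 h. In controls the median change of these genes from 0 to 24 h was -0.77, so part of this gap was seen in controls too. The range of values also differed between groups. Its measure, the interquartile range of all genes on an array, averaged 3.01 ± 0.03 (SD, n = 3) in controls and 2.97 ± 0.09 in Cebpa-deleted cells at 0 h. At 2 h it was 2.25 ± 0.13 in controls and 2.35 ± 0.20 in Cebpa-deleted cells. At 24 h it was 2.47 ± 0.04 in controls and 1.95 ± 0.16 in Cebpa-deleted cells, the narrowest of the 6 groups. The 6 arrays at 0 h all had a wider range than the 12 later arrays. Their lowest values (2.18 to 2.30) lay below those of the later arrays (2.74 to 2.89), and their highest values (14.53 to 14.62) lay above (13.7 to 13.88). Whether the 0 h arrays were normalized apart or the cells changed is not given, and each time may also be a batch. Arrays of 1 group correlated with r between 0.978 and 0.995 across genes, and 0 h arrays correlated with later ones with r between 0.919 and 0.982. The first principal component held 71.3% of the variance.

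**Figure D1:**
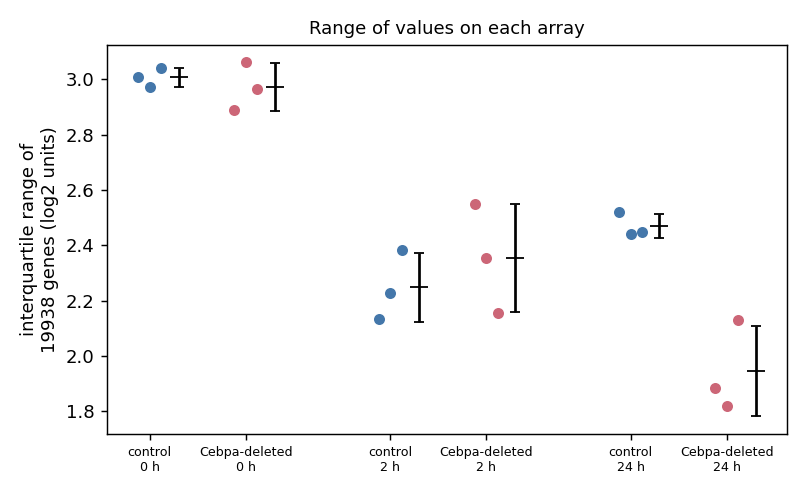
Interquartile range of the log2 values of 19938 genes on each of the 18 arrays, by genotype and hours of hyperoxia; dots are arrays, and the bar is the mean with SD of the 3 arrays of a group. The Cebpa-deleted 24 h arrays lie between 1.82 and 2.13.

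Cebpa itself was lower in the Cebpa-deleted cells at 2 h and at 24 h. Its level was 9.42 ± 0.52 (SD, n = 3) against 10.52 ± 0.14 in controls at 2 h, a log2 change of -1.10 (SE 0.18, 95% interval -1.48 to -0.73, adjusted p = 0.00461), which leaves 46.6% of the control level. At 24 h it was 8.43 ± 0.20 against 10.27 ± 0.17, a log2 change of -1.83 (SE 0.18, adjusted p = 8.19e-06), or 28.1% of the control level. Before hyperoxia it was 10.56 ± 0.12 against 10.99 ± 0.05, a difference of -0.43 (SE 0.18, 95% interval -0.8 to -0.06, unadjusted p = 0.0265). Adjusted over all genes this difference did not pass (adjusted p = 0.429), although the 3 Cebpa-deleted arrays at 0 h were below the 3 control arrays. The difference was larger at 24 h than at 0 h by -1.41 on the log2 scale (adjusted p = 0.00747 for the interaction), while at 2 h the corresponding value was -0.67 (adjusted p = 0.65). Averaged over the times, Cebpa fell by 1.12 on the log2 scale (SE 0.10, adjusted p = 6.53e-06). Cebpa also fell in controls, by 0.46 from 0 to 2 h (adjusted p = 0.0265) and by 0.72 from 0 to 24 h (adjusted p = 0.00211), between arrays of different range. Where the probes lie relative to the deleted part of the gene is not given, so the array need not show the full loss. With the array range as a covariate the 24 h difference was -1.30 (SE 0.29, adjusted p = 0.138) and no longer passed, and with only the 6 arrays at 2 h in the fit the 2 h difference had an adjusted p of 0.173.

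**Figure D2:**
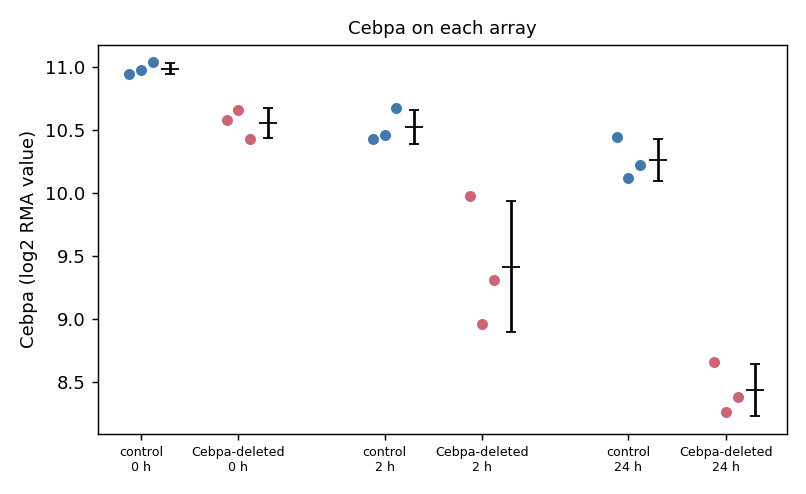
Cebpa on each of the 18 arrays as the log2 RMA value, by genotype and hours of hyperoxia; dots are arrays, and the bar is the mean with SD of the 3 arrays of a group. Controls lie between 10.12 and 11.04, and the Cebpa-deleted 24 h arrays lie between 8.26 and 8.66.

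Other members of the C/EBP family changed less than Cebpa at 2 and 24 h, although some passed. Cebpg, a family member that lacks the activation domain of the others, rose at 2 h by 0.51 (SE 0.12, adjusted p = 0.0357) and averaged over times by 0.25 (adjusted p = 0.017), with a value of 0.46 at 0 h (adjusted p = 0.08) and of -0.21 at 24 h (adjusted p = 0.137). Its 24 h difference was lower than its 0 h difference (interaction -0.67, adjusted p = 0.0218). Cebpe rose by 0.31 at 24 h (adjusted p = 0.0365), a call that was kept in only 1 of the 6 fits that each left out an array, the one without Cebpa-deleted replicate 4. Cebpb differed by 0.26, 0.13 and -0.26 at 0, 2 and 24 h, none of which passed (adjusted p = 0.454, 0.76 and 0.0593), although its 24 h difference was lower than its 0 h difference (interaction -0.51, adjusted p = 0.0395). Cebpd differed by -0.28, 0.13 and -0.23, with none past the threshold.

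Before hyperoxia, Cebpa-deleted isolates carried more transcript of endothelial genes. Cdh5, the cadherin of endothelial junctions, was 9.92 ± 0.19 against 8.74 ± 0.22 in controls, a rise of 1.19 (SE 0.24, adjusted p = 0.0247). Ecscr, an endothelial surface protein, rose by 1.16 (SE 0.17, adjusted p = 0.00543), Emcn, the endothelial sialomucin, by 1.10 (SE 0.25, adjusted p = 0.0381), Cd34 by 1.01 (SE 0.22, adjusted p = 0.0343) and the TGF-β co-receptor Eng by 0.99 (SE 0.22, adjusted p = 0.0343). Of the 16 measured endothelial markers 7 rose, 0 fell and 9 did not pass; adjusted over the list alone, 15 rose. The list's median was 0.91 and its adjusted p was 3.23e-22 with the preset correlation; the adjusted p = 0.213 with an estimated correlation. This list was also called in each of the 6 fits that left out an array.

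Besides Cdh5 and Ecscr, the largest rises at 0 h, in genes whose 3 Cebpa-deleted arrays all lay above the 3 control arrays, were of A4gnt, a glycosyltransferase (1.43, SE 0.31, adjusted p = 0.0307), the drug efflux pump Abcg2 (1.37, SE 0.18, adjusted p = 0.00257), Tecrl (1.28, SE 0.26), Mctp1 (1.25), Hepacam (1.23), Olfr767 (1.21), the sodium channel gene Scn7a (1.21, SE 0.26) and Slfn5 (1.17). Chance alone separates 3 arrays from 3 in 10% of genes. The largest falls were of Usp17ld, a deubiquitinase (-1.55, SE 0.27, adjusted p = 0.013), the histone gene H3c15 (-1.42), the cytochrome P450 gene Cyp1b1 (-1.10, SE 0.19, adjusted p = 0.012), Il1f9, which encodes interleukin 36γ (-1.01, SE 0.22), and Gdpd2, a glycerophosphodiesterase (-0.93, SE 0.15, adjusted p = 0.00748). The others were Mir191 (-1.02), Mir19b-1 (-1), Snord82 (-0.99), Snord52 (-0.94) and AY512931 (-0.86). From other lists, the flavin monooxygenase Fmo1 rose by 0.97, the complement gene C1qb by 0.79, the interferon-inducible Gbp3 by 0.75, Il1b by 0.68 and the p53 target Eda2r by 0.57 (adjusted p between 0.0188 and 0.0343 for these genes).

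Smaller shifts appeared in other cell lists at 0 h. None of the 21 type II cell genes passed alone, but the list lay lower, with a median of -0.13 (adjusted p = 0.0198). The macrophage markers lay higher at 0.20 (1 of 19 rose, adjusted p = 0.0198), the type I cell markers at 0.33 (0 of 15 rose, adjusted p = 0.0374) and the fibroblast and smooth muscle markers at 0.32 (0 of 16 rose, adjusted p = 0.0403). With an estimated correlation the adjusted p of type II cell genes was 0.973, and no list was called at 0 h. These 4 lists were no longer called without Cebpa-deleted replicate 3.

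In all, 171 genes differed at 0 h, of which 135 were higher and 36 lower. The count depended on single arrays: it was 107, 36 and 57 without control replicates 1, 2 and 3, and 32 and 46 without Cebpa-deleted replicates 2 and 3. Of 28 named genes called at 0 h, only Abcg2, Ecscr and Gdpd2 were called in every such fit, and after a second quantile normalization 8 of the 171 genes passed.

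After 2 h of hyperoxia the same direction held for endothelial genes. Cdh5 was 10.22 ± 0.69 against 8.77 ± 0.23 (1.45, SE 0.24, adjusted p = 0.00592). Cd93 rose by 1.64 (SE 0.30, adjusted p = 0.0099), the sphingosine-1-phosphate receptor S1pr1 by 1.38 (SE 0.26, adjusted p = 0.0106), Eng by 1.36 (SE 0.22, adjusted p = 0.00441), Tek, the angiopoietin receptor, by 1.28 (SE 0.22, adjusted p = 0.0069) and Cd34 by 1.13. Of the 16 endothelial markers 12 rose, 0 fell and 4 did not pass, with 15 higher when adjusted over the list alone. Their median was 0.97 (adjusted p = 1.24e-23, and adjusted p = 0.172 with an estimated correlation). The mean of these markers lay between 8.51 and 9.36 on the Cebpa-deleted 2 h arrays and between 7.96 and 8.23 on the controls.

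Among the genes that fell at 2 h were Il1f9 (-1.30, SE 0.22, adjusted p = 0.00684), Pon1, a paraoxonase found in Clara cells (-1.26, SE 0.17, adjusted p = 0.00168), Vnn1, a pantetheinase (-1.15, SE 0.21, adjusted p = 0.00968), the complement gene C6 (-1.14, SE 0.20, adjusted p = 0.00835), Gdpd2 (-1.13, SE 0.15, adjusted p = 0.00168) and Il6 (-1.02, SE 0.22, adjusted p = 0.022). The acidic chitinase Chia1 fell by 0.99 (SE 0.21), the alarmin Il33 by 0.99 (SE 0.23, adjusted p = 0.0403) and the integrin Itga9 by 0.97 (SE 0.20, adjusted p = 0.0202). Besides Cdh5, Cd93, S1pr1 and Eng, the largest rises were of Tecrl (1.89, SE 0.26, adjusted p = 0.00168), Scn7a (1.65, SE 0.26, adjusted p = 0.00441), Tcim (1.47), Hepacam (1.47), Adgrl4 (1.35) and BC028528 (1.32). In each of these genes the 3 arrays of 1 genotype lay above the 3 of the other.

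Type II cell and lipid genes lay slightly lower at 2 h. Of 21 type II cell genes 2 fell, Il33 and the growth factor receptor Fgfr2 (-0.55, SE 0.13, adjusted p = 0.0382), and 19 did not pass; 5 fell when adjusted over the list alone, and the median was -0.15 (adjusted p = 0.00125). Cholesterol synthesis had a median of -0.24 with 0 of 19 genes past the threshold (adjusted p = 0.000539). Fatty acid synthesis had a median of -0.13 with 0 of 18 (adjusted p = 0.0117), and phospholipid and triglyceride handling a median of -0.12 with 1 of 19, the acyltransferase Gpam (-0.81, SE 0.18, adjusted p = 0.0309). For these 4 lists the adjusted p = 0.706 with an estimated correlation. With the array range as a covariate their medians were -0.26, -0.43, -0.33 and -0.22, with 11, 7, 7 and 4 members lower.

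Lists of other cells and of interferon genes lay higher at 2 h. The macrophage markers had a median of 0.50 (0 of 19 rose, and 7 when adjusted over the list alone; adjusted p = 8.7e-08, and adjusted p = 0.354 with an estimated correlation). Fibroblast and smooth muscle markers had a median of 0.42, with the matrix proteoglycan Bgn higher by 0.98 (SE 0.19, adjusted p = 0.0119) as 1 of 16 (list adjusted p = 8.7e-08, and adjusted p = 0.307 with an estimated correlation). The interferon response had a median of 0.20, with Oasl2 higher by 0.64 (adjusted p = 0.0296) and the antiviral gene Rsad2 by 0.60 (adjusted p = 0.0117), which made 2 of 17, and 6 when adjusted over the list alone (list adjusted p = 3.21e-06, and adjusted p = 0.182 with an estimated correlation). MHC class II genes (median 0.33, 0 of 8 rose, adjusted p = 0.00554), lymphocyte markers (0.28, 0 of 14, adjusted p = 0.00618), transitional epithelial genes (0.12, 0 of 17, adjusted p = 0.00449), apoptosis regulators (0.14, 0 of 18, adjusted p = 0.0138), cell cycle genes (0.08, 0 of 22, adjusted p = 0.0138) and p53 targets (0.05, adjusted p = 0.0167) shifted less, none called with an estimated correlation. The p53 target that rose was the death receptor gene Tnfrsf10b (0.64, adjusted p = 0.0102), 1 of 17. Single xenobiotic genes rose or fell, with Fmo1 higher by 1.02 (adjusted p = 0.0166) and the aldehyde oxidase Aox3 lower at -0.91 (adjusted p = 0.0117), and their list was not called.

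In total 280 genes differed at 2 h, 239 higher and 41 lower, so 85.4% of calls were higher. After quantile normalization 72.3% of the calls were higher (251 against 96), and with the array range as a covariate 56.4% were (563 against 436, including all 280). The count was 167 without control replicate 1 or 2, 54 without control replicate 3, 729 without Cebpa-deleted replicate 2 and 25 without Cebpa-deleted replicate 3, and 1 gene passed when only the 6 arrays at 2 h were fitted. Of the 30 named genes Tecrl, Pon1, Gdpd2 and BC028528 were called in every fit without an array, as was Cebpa, and of the 14 lists the endothelial, macrophage, fibroblast and interferon lists were.

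**Figure D3:**
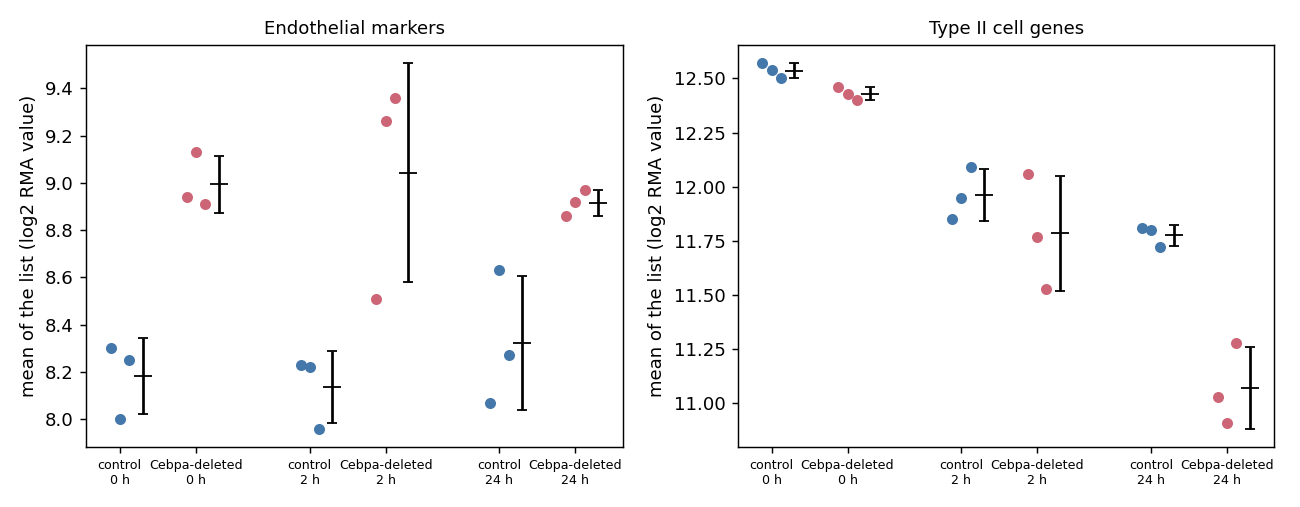
Mean log2 RMA value of the 16 endothelial markers (left) and of the 21 type II cell genes (right) on each of the 18 arrays, by genotype and hours of hyperoxia; dots are arrays, and the bar is the mean with SD of the 3 arrays of a group. At 0 h the endothelial mean lies between 8.00 and 8.30 in controls and between 8.91 and 9.13 in Cebpa-deleted cells.

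At 24 h Lcn2, Itih4 and Chil1 had the largest falls in Cebpa-deleted cells. Lcn2, a siderophore-binding defence protein, was 9.41 ± 0.56 against 11.82 ± 0.20 in controls (-2.40, SE 0.22, adjusted p = 6.92e-06). The acute phase gene Itih4 fell by 2.13 (SE 0.32), the chitinase-like Chil1 by 2.12 (SE 0.43), the chitinase Chia1 by 2.04 (SE 0.21, adjusted p = 9.62e-06), the TNF family ligand Tnfsf9 by 2.04 (SE 0.26), C6 by 1.98 (SE 0.20), Il6 by 1.98 (SE 0.22, adjusted p = 2.19e-05) and Itga9 by 1.95 (SE 0.20). Ndnf (-2.02) and Pof1b (-2.01) complete the 10 largest falls. Among the genes with the largest rises were several expressed in lymphocytes, namely the interleukin 7 receptor Il7r (1.75, SE 0.32, adjusted p = 0.000599), the granzyme Gzma (1.62, SE 0.27), Satb1 (1.61) and Gimap3 (1.55, SE 0.27). Srsy (2.18, SE 0.22), Mir680-2 (1.74), Olfr485 (1.58), Mir680-1 (1.52), Scn7a (1.52) and the methyltransferase Inmt (1.51, SE 0.45), not called without Cebpa-deleted replicate 4 (1.13), were the others. For each of these 20 genes the 3 arrays of 1 genotype lay above the 3 of the other. The range of values was narrower on these Cebpa-deleted arrays, by 0.53 in the mean interquartile range.

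At 24 h lists of type II cell genes and of lipid metabolism were lower. Of 21 type II cell genes 19 fell, 1 rose and 1 did not pass, with 20 lower when adjusted over the list alone and a median of -0.75 (adjusted p = 8.77e-09). Sftpd, which encodes surfactant protein D, was 11.24 ± 0.38 against 12.44 ± 0.17 (-1.20, SE 0.15, adjusted p = 6.3e-05). Lpcat1, which remodels surfactant phosphatidylcholine, fell by 1.01 (SE 0.14, adjusted p = 0.000123), Il33 by 1.32 (SE 0.23) and the protease gene Ctsc by 1.05 (SE 0.13). Cholesterol synthesis had the lowest median of the 31 lists, at -1.19, with 18 of 19 genes lower (adjusted p = 5.8e-10). Its largest falls were of Cyp51 (-1.81, SE 0.27, adjusted p = 0.00017), Lss (-1.71, SE 0.26) and Idi1 (-1.57, SE 0.22). Of 19 genes for phospholipid and triglyceride handling 17 fell (median -0.69, adjusted p = 8.55e-08), among them the fatty acid carrier Fabp5 (-1.69, SE 0.24), Gpam (-1.31), the lipid droplet coat gene Plin2 (-1.27, SE 0.15, adjusted p = 3.25e-05) and Lpin1 (-1.18). In fatty acid synthesis 15 of 18 fell and 1 rose (median -0.75, adjusted p = 1.91e-05), with Insig1 at -1.40 and acetyl-CoA carboxylase, Acaca, at -1.28. For all of these lists the adjusted p = 0.425 with an estimated correlation.

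Lists of energy and stress pathways were also called lower at 24 h. Most were not unusually low beside 2000 random lists of matched mean level. Percentiles were 2.15 for fatty acid oxidation, 12.3 for oxidative phosphorylation, 14.4 for hypoxia and glycolysis, 15.5 for glucocorticoid targets and 21.85 for antioxidant enzymes. They were 34.6 for the unfolded protein response, 76.2 for heat shock genes, 96.45 for immediate early genes and 99.05 for NRF2 targets. A high percentile means a higher median than most matched lists. Oxidative phosphorylation fell in 19 of 21 genes (median -0.42, adjusted p = 1.88e-06), such as Cox7a2 (-0.71) and Ndufb5 (-0.69), and fatty acid oxidation in 14 of 18 with 1 higher (median -0.48, adjusted p = 0.000209). The unfolded protein response fell in 15 of 20 (median -0.37, adjusted p = 8.69e-05), including Asns (-0.99) and Dnajb9 (-0.78). Heat shock genes fell in 6 of 13 (median -0.29, adjusted p = 0.00262), including Hspa1a (-1.37) and Hspb1 (-1.04). Antioxidant enzymes went both ways, with 11 of 19 lower, such as Gpx1 (-1.08, SE 0.18) and Prdx3 (-0.93), and 2 higher, the secreted enzymes Gpx3 (0.86) and Sod3 (0.58), at a median of -0.36 (adjusted p = 0.00655). NRF2 targets fell in 6 of 20 with 1 higher (median -0.17, adjusted p = 0.0261), the falls including the NADPH-producing Me1 (-0.71) and Tkt (-0.71). This list's median was 0.18 and not called after quantile normalization, and without control replicate 3 or Cebpa-deleted replicate 1 its adjusted p was 0.0523 and 0.0524. Immediate early genes fell in 8 of 22 (median -0.21, adjusted p = 0.0136), with Atf3 at -0.94 and Fosb at -0.93; their median was 0.08 and not called after quantile normalization, and -0.07 without Cebpa-deleted replicate 2 (adjusted p = 0.056). Hypoxia and glycolysis fell in 9 of 16 (median -0.36, adjusted p = 0.0141) and glucocorticoid targets in 8 of 15 (median -0.37, adjusted p = 0.0141). None of these lists was called with an estimated correlation (adjusted p between 0.425 and 0.451). With the range covariate the direction turned for oxidative phosphorylation (median 0.06), Prdx3 (0.05) and Tkt (0.11) and, by the sign of their test, for fatty acid oxidation (median 0) and antioxidant enzymes (-0.05), none of them called.

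Marker genes of other cells moved apart at 24 h. Type I cell markers fell in 12 of 15 (median -0.70, adjusted p = 4.82e-05), with Rtkn2 at -1.85 (SE 0.52) and Igfbp2 at -1.69 (SE 0.36). Lymphocyte markers rose in 9 of 14 (median 0.68, adjusted p = 0.00176), among them Gzma and the surface antigen Cd2 (0.99). Endothelial markers rose in 13 of 16 with 1 lower (median 0.68, adjusted p = 0.00162), such as Tek (1.15, SE 0.22) and the VEGF receptor Kdr (0.96). Fibroblast and smooth muscle markers rose in 11 of 16 with 1 lower (median 0.74, adjusted p = 0.00669), including Dcn (1.25) and Pdgfra (1.24, SE 0.19). Neutrophil markers rose in 6 of 13 (median 0.31, adjusted p = 0.0103), with Ltf at 1.08, a gene not called without control replicate 2 or 3 or Cebpa-deleted replicate 1 or 4. With an estimated correlation these 5 lists had adjusted p between 0.425 and 0.448. With the range covariate the 4 lists that rose were not called, at medians of -0.04 for lymphocyte, 0.10 for endothelial, 0 for fibroblast and 0.07 for neutrophil markers; after quantile normalization the first 3 were called, at 0.52, 1.03 and 0.83, and the neutrophil list was not (0.08).

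Other lists were not called at 24 h, although single members passed. In cytokines, chemokines and NF-κB targets 9 of 21 fell and 2 rose (median -0.25, adjusted p = 0.0529), with the neutrophil chemokine Cxcl5 higher by 1.38, though not without control replicate 2 (0.85). Of 17 p53 targets 7 fell and 2 rose (median -0.23, adjusted p = 0.0518), with Sesn2 at -0.82 and Perp at -0.71. In the MHC class II list H2-Ab1 fell by 0.76, not called without control replicate 3 or Cebpa-deleted replicate 1 or 2 and at 0.39 with the range covariate, and H2-Ob rose by 0.71 (list median -0.45, adjusted p = 0.369). Xenobiotic metabolism had a median of 0.14 and a mean of -0.08 (adjusted p = 0.953), with Cyp2b10 at -1.68 and Aox3 at -1.38. The cell cycle list stayed at a median of 0.05, and within it the mitotic kinase Bub1 fell by 1.32. The Clara cell list was at 0.34, although its member Pon1 fell by 1.25, and ciliated (0.18), macrophage (0.21), erythroid (0.26), interferon (0.09), apoptosis (-0.13), circadian clock (-0.21) and transitional epithelial (-0.21) lists were not called either.

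The 24 h comparison called 10110 genes, 4852 higher and 5258 lower, of which 2579 changed at least 1.5-fold, 1038 up and 1541 down. With each array centred on its median 37.3% of calls were higher (3606 against 6069), in place of 48.0%. The count was 6128 without Cebpa-deleted replicate 2 and 217 without replicates 1 and 2, the narrowest arrays. With the array range as a covariate 4 genes passed, Vsig2 (0.83), Morc4 (-1.47), Col12a1 (-1.36) and Ctsz (-0.94), which are named here because they are the only ones; the median size of the change of the 10110 genes went from 0.45 to 0.13, and none of the 65 genes named at 24 h was called. Under that covariate the median was -0.34 for cholesterol synthesis (adjusted p = 0.00274), -0.27 for phospholipid handling (adjusted p = 0.00274), -0.13 for type II cell genes (adjusted p = 0.017) and -0.45 for type I cell markers (adjusted p = 0.00378), which were still called. It was -0.04 for fatty acid synthesis, 0.06 for oxidative phosphorylation and 0.10 for endothelial markers, which were not. Of 8 lists called with the covariate, 7 were lower and 1 higher. Those not called without it were transitional epithelial genes (-0.31, adjusted p = 7.7e-06), p53 targets (-0.24, adjusted p = 0.00145) and cytokines, chemokines and NF-κB targets (-0.13, adjusted p = 0.00378). The list called higher was MHC class II (0.28, adjusted p = 0.00738).

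**Figure D4:**
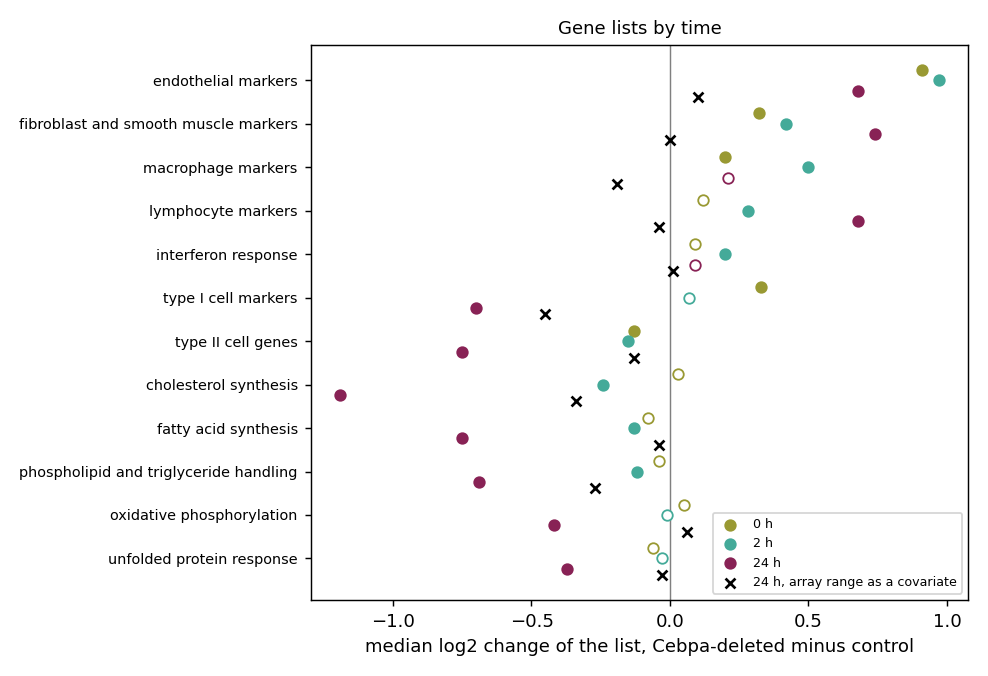
Median log2 change, Cebpa-deleted minus control, of 12 gene lists at 0, 2 and 24 h of hyperoxia (horizontal axis); filled circles are lists called with the preset correlation, open circles are not, and crosses are the 24 h median with the array range as a covariate. Endothelial markers lie at 0.91, 0.97 and 0.68 in turn, and cholesterol synthesis at 24 h moves from -1.19 to -0.34 with the covariate.

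A core of genes differed in the same direction at every time, in comparisons that share no arrays but share the estimate of the spread. At 0, 2 and 24 h alike 62 genes were higher, including the endothelial genes Cdh5, Cd34, Emcn, Ecscr, Eng, Kdr and Pecam1 as well as Abcg2, Scn7a, Hepacam and Fmo1. Erg, Acvrl1 and Ldb2, members of a second endothelial list described below, were also among them. RNA from endothelial cells in the isolates was not separated from expression in type II cells. The set of higher genes therefore need not depend on Cebpa in type II cells. The 4 lower at every time were Gdpd2, Il1f9, the kinase gene Dclk1 and the retinol carrier Rbp4, listed because they are few. Between 0 and 2 h 73 higher genes were shared, where independent lists would share 1.62, and 4 lower genes, where they would share 0.074. Between 0 and 24 h 97 higher and 12 lower genes were shared (32.9 and 9.49 for independent lists), and between 2 and 24 h 137 higher and 35 lower (58.2 and 10.8). These expected numbers leave out the shared spread, and with only the arrays of the groups compared in each fit the shared calls numbered 0, 115 and 1, since 1 gene passed at 2 h. Across all genes, which are not independent replicates, the changes at 0 and 2 h correlated with r = 0.40, those at 0 and 24 h with r = 0.32 and those at 2 and 24 h with r = 0.07. With the array range as a covariate the shared calls numbered 130, 0 and 2 for the 3 pairs of times.

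Averaged over the times, Scn7a rose by 1.46 (SE 0.15, adjusted p = 8.93e-06), Cd93 by 1.28, the adrenomedullin receptor subunit Calcrl by 1.22 (SE 0.12, adjusted p = 7.09e-06), Slfn5 by 1.21, Rasgrp3 by 1.20, Hepacam by 1.19, Cdh5 by 1.18 (SE 0.14, adjusted p = 3.24e-05), Cyyr1 by 1.16, BC028528 by 1.12 and Tek by 1.11. C6 fell by 1.28 (SE 0.12, adjusted p = 6.53e-06), Chia1 by 1.20 (SE 0.12, adjusted p = 7.91e-06), Il1f9 by 1.19, Lcn2 by 1.19, Il6 by 1.13, Itga9 by 1.12, Tnfsf9 by 1.08, the calcium-binding S100g by 1.06 and Vnn1 by 1.06. Each of these genes had a mean difference of the same sign at the 3 times. Among type II cell genes 15 of 21 fell and 1 rose (median -0.31, adjusted p = 8.35e-11), with Il33 at -0.87, Sftpd at -0.65 (SE 0.09) and Fgfr2 at -0.63 (SE 0.07). In cholesterol synthesis 14 of 19 fell (median -0.50), with Cyp51 at -0.78 and Idi1 at -0.70, and in phospholipid handling 12 of 19 fell (median -0.30), with Fabp5 at -0.86 and Gpam at -0.79. Endothelial markers rose in 14 of 16 (median 0.88, adjusted p = 6.61e-15), fibroblast and smooth muscle markers in 10 of 16 (median 0.57) and interferon response genes in 6 of 17 (median 0.15). In total 16 lists were called for the average, the smallest adjusted p with an estimated correlation being 0.35.

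The average called 3366 genes, 1422 higher and 1944 lower, or 42.2% higher, against 27.6% with arrays centred on their median and 54.3% with the range covariate, under which 796 passed. Without 24 h, 591 genes passed, 468 higher and 123 lower. The count was 2163 without control 2 h replicate 3, 5783 without Cebpa-deleted 2 h replicate 2, 2209 without Cebpa-deleted 24 h replicate 2 and 5057 without Cebpa-deleted 24 h replicate 4. All 28 named genes called for the average stayed called in each of the 18 fits without an array, but without 24 h 8 of the 28 lost their call and 20 kept it.

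Between 2 and 24 h of hyperoxia, NRF2 and p53 targets rose in controls. This comparison was added after the data were seen, and each time may also be a batch. Against 0 h neither list was higher in controls at 24 h. The medians were -0.05 for NRF2 targets (adjusted p = 0.801) and -0.24 for p53 targets (adjusted p = 0.872). With the range covariate they were -0.06 and -0.20, so neither list as a whole rose above its level before hyperoxia. Members went both ways against 0 h, with 2 NRF2 targets called higher and 5 lower, and 3 p53 targets higher and 6 lower. From 2 to 24 h NRF2 targets rose in 7 of 20 genes and 9 when adjusted over the list alone (median 0.32, adjusted p = 1.92e-06, and adjusted p = 0.397 with an estimated correlation). Among them were the quinone reductase Nqo1 (0.82, SE 0.14, adjusted p = 0.000749), the ferritin gene Ftl1 (0.49, SE 0.08) and Me1 (0.49). Of 17 p53 targets 5 rose (median 0.16, adjusted p = 0.000156, and adjusted p = 0.202 with an estimated correlation), with Ccng1 at 0.92 (SE 0.08, adjusted p = 2.46e-06), Phlda3 at 0.69 (SE 0.13) and Zmat3 at 0.47. Both lists were called in every fit without an array and with the range covariate, at medians of 0.29 and 0.29. Cholesterol synthesis rose in 10 of 19 with 1 lower (median 0.54, adjusted p = 4.07e-06), including Cyp51 (1.21, SE 0.27), Lss (1.02) and Idi1 (0.87), and type I cell markers rose in 7 of 15 (median 0.71, adjusted p = 0.000261), including Akap5 (1.47), Spock2 (1.44) and Igfbp2 (1.32). Neither of this pair was called with an estimated correlation (adjusted p = 0.815) or with the range covariate, at medians of 0.20 and 0.45 (adjusted p = 0.0921 and 0.0547).

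Ciliated cell, Clara cell and lymphocyte markers fell in controls over the same interval. Ciliated cell markers fell in 6 of 15 (median -0.37, adjusted p = 0.0139), with Lrrc23 at -0.71 and the dynein gene Dnali1 at -0.64, Clara cell markers in 3 of 12 (median -0.31, adjusted p = 0.0261), with Chad at -0.96 and Pon1 at -0.86, and lymphocyte markers in 4 of 14 (median -0.47, adjusted p = 0.0319), with Gzma at -1.33. These lists were not called with an estimated correlation (adjusted p = 0.815), with the range covariate, or without control 24 h replicate 2. The largest single rises were of Lsmem1 (2.91, SE 0.19, adjusted p = 9.07e-08), the actin-severing Scin (2.34), Tas2r135 (2.18), the decoy receptor Il13ra2 (2.00, SE 0.15, adjusted p = 3.54e-07) and Eid3 (1.90), and the largest falls of Srsy (-1.74) and Nnat (-1.71), with Il33 also lower (-1.46). In all 2480 genes changed, 1590 up and 890 down, or 64.1% up; with the range covariate 2785 passed with 44.3% up (1235 against 1550), of which 1452 were the same genes. Without control 2 h replicate 1 or 2 the count was 1398 and 1558, and without control 24 h replicate 1 or 3 it was 1425 and 1477. The calls of Lss, Idi1, Akap5, Spock2, Igfbp2 and Dnali1 were lost without control 2 h replicate 1 or 2 and without control 24 h replicate 2 or 3, that of Spock2 also without control 24 h replicate 1, and those of Me1 and Lrrc23 without control 2 h replicate 1.

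In Cebpa-deleted cells the change from 2 to 24 h was also added after the data were seen. Type II cell genes fell in 18 of 21 (median -0.65, adjusted p = 2.71e-10), the unfolded protein response in 13 of 20 (median -0.46, adjusted p = 1.1e-06) and MHC class II genes in 6 of 8 (median -0.79, adjusted p = 0.0162). Chil1 (-2.23), Itih4 (-1.79), Il33 (-1.79), the chitinase-like Chil3 (-1.68) and Chia1 (-1.66) fell most, while Lsmem1 (1.87), Cxcl5 (1.46), Phxr4 (1.44), Srsy (1.30) and Tbrg3 (1.28) rose most, with Cxcl5 not called without Cebpa-deleted 2 h replicate 2 (1.06) or 24 h replicate 1 (1.33). Cebpa fell by 0.98 in these cells (adjusted p = 0.00093), against a value of -0.25 in controls that did not pass (adjusted p = 0.362). All 16 lists called were lower, against 6 lower and 1 higher after quantile normalization, none with an estimated correlation (smallest adjusted p = 0.591), and the range of values was narrower at 24 h in these cells. Cholesterol synthesis was one of them, at a median of -0.34 with 6 of 19 lower; with the range covariate its median was 0.24 and it was called higher (adjusted p = 1.82e-05). Fatty acid synthesis, antioxidant enzymes and oxidative phosphorylation also turned direction with the covariate, from medians of -0.56, -0.22 and -0.32 to 0.05, 0.04 and 0.07, none of them called. Of 6254 genes 2355 rose and 3899 fell, so 37.7% rose; after quantile normalization 49.95% did (2608 against 2613), and with the range covariate 115 passed. Without Cebpa-deleted 24 h replicate 1 or 2 the count was 3538 and 2922, and without 2 h replicate 2 it was 3111.

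The tests of whether the change over time differed by genotype called many genes at 24 h and no gene at 2 h. For 0 to 24 h, 2859 genes differed, 1089 more positive and 1770 more negative in Cebpa-deleted cells. Usp17ld (2.17), Satb1 (1.68) and Il7r (1.66) had the largest positive differences, and Rtkn2 (-2.56), the guidance molecule Sema3a (-2.42) and Chil1 (-2.25) the largest negative ones. Of these, Usp17ld and Sema3a were called in each of the 12 fits without an array. Cholesterol synthesis differed by a median of -1.28 (15 of 19 lower), type I cell markers by -1.05 (10 of 15) and type II cell genes by -0.66 (12 of 21), NRF2 targets by -0.31 (4 of 20) and p53 targets by -0.21 (4 of 17), while lymphocyte markers differed by 0.70 with 0 of 14 past the threshold. The smallest adjusted p with an estimated correlation was 0.397. With the range covariate 1 gene passed, but cholesterol synthesis (-0.39, adjusted p = 0.000137), type I cell markers (-0.88, adjusted p = 1.83e-05), NRF2 targets (-0.21, adjusted p = 0.00253) and p53 targets (-0.36, adjusted p = 1.64e-05) were still called. The count ran from 278 without Cebpa-deleted 24 h replicate 2 to 5828 without Cebpa-deleted 24 h replicate 4, and of the 12 arrays only Cebpa-deleted 0 h replicate 1 could be left out with a change under 1.5 times. After quantile normalization 48.7% of calls were positive (591 against 622), in place of 38.1%.

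For 0 to 2 h limma called 0 genes for a difference by genotype, with 1279 at an unadjusted p below the same threshold. The genes nearest to it were Cyp1b1 (1.28), C1s2 (1.22), Prame (0.73), Srsy (-1.61), n-R5s136 (-1.04) and Ssx9 (-0.86), none past it (adjusted p = 0.494). As lists, cholesterol synthesis differed by -0.25 (adjusted p = 0.0121), the interferon response by 0.14 (adjusted p = 0.0225) and fibroblast and smooth muscle markers by 0.22 (adjusted p = 0.0272), with no single member past the threshold and adjusted p = 0.926 with an estimated correlation. Each of the 3 was lost without at least 1 of the arrays, and 0 lists were called without control 2 h replicate 3.

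Compared with 0 h, the lists called at 2 and 24 h were nearly all lower, 14 of 14 and 12 of 12 in controls and 14 of 15 and 15 of 16 in Cebpa-deleted cells, on arrays of a narrower range. This rested on the deposited scaling: after quantile normalization 0 lists were lower and 1 higher in controls at 2 h, 1 lower and 1 higher at 24 h, and in Cebpa-deleted cells 3 lower and 2 higher at 2 h and 7 lower and 3 higher at 24 h. In controls at 2 h, type II cell genes fell in 17 of 21 with 1 higher (median -0.71, adjusted p = 0.00188), cholesterol synthesis in 16 of 19 (median -0.70, adjusted p = 0.00369) and oxidative phosphorylation in 20 of 21 (median -0.71, adjusted p = 2.75e-05). With the range covariate their medians were 0.16, 0.47 and 0.06, so the direction turned. By the list test cholesterol synthesis was then called higher (adjusted p = 8.74e-05). Type II cell genes and oxidative phosphorylation were not called (adjusted p = 0.065 and 0.87). After quantile normalization the medians were -0.07, -0.20 and -0.19, none called. In Cebpa-deleted cells at 2 h, cholesterol synthesis fell in 19 of 19 (median -0.89) and oxidative phosphorylation in 21 of 21 (median -0.68), at medians of 0 and -0.17 with the covariate, neither called. At 24 h type II cell genes fell in 19 of 21 in controls (median -0.77) and in 20 of 21 in Cebpa-deleted cells (median -1.40), and oxidative phosphorylation in 17 of 21 (median -0.69) and 21 of 21 (median -1.20). With the covariate these lists were not called, at -0.31 and -0.33 for the first and -0.15 and -0.21 for the second; after quantile normalization they were called only in Cebpa-deleted cells (-0.58 and -0.42). Cell cycle genes fell in controls in 13 of 22 (median -0.42, adjusted p = 0.0102), also with the range covariate (-0.41, adjusted p = 0.0129). Transitional epithelial genes fell in Cebpa-deleted cells in 12 of 17 (median -0.47, adjusted p = 0.0246), with a median of 0.34 after quantile normalization. The adjusted p with an estimated correlation was at least 0.478 for every list in these comparisons.

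Single genes changed widely against 0 h. Srsy (2.87), Tmem92 (2.76), Snord47 (-2.79) and Zfp931 (-2.56) changed most in controls at 2 h, and Tas2r135 (2.14), Olfr270 (2.08), Usp17ld (-3.06) and Zfp931 (-2.34) at 24 h. In Cebpa-deleted cells Tmem92 (2.28), the antimicrobial lectin Reg3g (2.18), Bex2 (-2.60) and Alkal1 (-2.09) changed most at 2 h, and Tmem92 (3), Olfr270 (2.59), Itih4 (-3.24) and Alkal1 (-3.08) at 24 h. With the range covariate Alkal1 had values of 0.86 and 1.82, neither called. The number of genes called was 13979 and 11939 in controls at 2 and 24 h, and 12586 and 15468 in Cebpa-deleted cells, and with the range covariate it was 940, 3369, 1195 and 39. In controls at 24 h 42.2% of the calls were higher, against 51.4% with arrays centred on their median.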

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

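The tests of a lower share of type II cells and of the narrower range were chosen only after the result was seen, and the setting that removes the trend on the level was added after the data were seen.

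Several values drew attention because the change over time differed between genotypes by a test of the difference itself. From 0 to 24 h 2859 genes differed, among them Cebpa (-1.41), Usp17ld (2.17), Satb1 (1.68), Il7r (1.66), Rtkn2 (-2.56), Sema3a (-2.42) and Chil1 (-2.25). By the list test with its preset correlation lipid and type II cell lists differed over the same interval, although no list did with an estimated correlation (smallest adjusted p = 0.397, and 0.926 from 0 to 2 h), with medians of -0.66 for type II cell genes, -0.71 for fatty acid synthesis (0.05 with the range covariate), -1.28 for cholesterol synthesis, -0.64 for phospholipid and triglyceride handling and -0.52 for fatty acid oxidation. Stress and energy lists had medians of -0.31 for NRF2 targets, -0.35 for antioxidant enzymes, -0.21 for p53 targets, -0.29 for heat shock genes, -0.32 for the unfolded protein response, -0.37 for hypoxia and glycolysis, -0.49 for oxidative phosphorylation and -0.39 for glucocorticoid targets. Cell lists had medians of -0.25 for transitional epithelial genes (-0.05, with the sign of their test reversed, after quantile normalization), -1.05 for type I cell markers and 0.70 for lymphocyte markers. From 0 to 2 h the lists that differed were cholesterol synthesis (-0.25), the interferon response (0.14) and fibroblast and smooth muscle markers (0.22).

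Endothelial markers were higher in Cebpa-deleted isolates at 0 and 2 h, with medians of 0.91 and 0.97, and at 24 h with 0.68, which became 1.03 after quantile normalization but 0.10, not called, with the range covariate, and the list was not called at any time with an estimated correlation (adjusted p = 0.213, 0.172 and 0.448). A lower share of type II cells alone would raise the markers of all other cells alike. Instead, 6 of 6 lists of other cell types lay more than 0.3 below the endothelial median at 0 h, by differences from 0.60 to 1. These differences go against it as the whole cause but cannot exclude it. Some markers lay low in controls, such as S100a9 (5.77) and Trem1 (6.27), near an array's lower quartile (5.62 for replicate 1), where a rise may be damped. Clara cells also carry the deletion. A candidate explanation is RNA from endothelial cells in the isolates: on a second endothelial list of 16 other genes, 100% were higher at 0 h and at 2 h, with medians of 0.74 and 0.60. The 4 members of the first list with the highest array values in controls at 0 h, which do not rank transcripts across probes, moved unequally, Pecam1 from 9 to 9.94, Cldn5 from 8.89 to 9.81 and Kdr from 8.88 to 9.80, but Esam, at 9.94 in controls and 9.96 in Cebpa-deleted isolates, did not rise with them. Whether expression changed within the isolated cells, or the deletion or the isolation left more endothelial cells among them, remains open, since the labels name no step that would remove such cells.

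At 24 h 10110 genes differed by genotype, on Cebpa-deleted arrays with the narrowest range. Across genes the change correlated with the control level (r = -0.60), but a change set only by that level is argued against as the whole cause. After quantile normalization and removal of the trend on it 6624 genes were called, which need not all be among the 10110. The narrower range fits the pattern by only 1 of its tests. Quantile normalization, which gives every array the same distribution, called 6697 genes, of which 4912 were among the 10110 in the same direction. With the array range as a covariate 4 were called, because the median size of the change fell from 0.45 to 0.13 while the median SE rose from 0.12 to 0.18. At 24 h the ranges of Cebpa-deleted arrays (1.82 to 2.129) and controls (2.441 to 2.52) did not overlap. The covariate's slope comes from differences within groups and is carried over that gap. The fall to 4 therefore cannot tell range from genotype. A slope on array range was fitted to the 2 h arrays of both genotypes, with a mean for each genotype. The changes it gives correlate with the 24 h changes across genes with r = 0.77, and 92.5% of the called genes lie in their direction. The range is computed from the same values, so part of this agreement is built in. The Cebpa-deleted 2 h arrays also differed in Cebpa and marker lists, so the slope need not reflect range alone. The slope gives a median of -0.69 of the -0.75 of type II cell genes and -0.89 of the -1.19 of cholesterol synthesis. It misses other lists, with 0.33 where p53 targets had -0.23 and 0.51 where transitional epithelial genes had -0.21. It gives 0.16 where cytokines, chemokines and NF-κB targets had -0.25, and -0.18 where type I cell markers had -0.70. Across genes the 24 h change rose by 0.66 per unit of the change it gives. RNA quality, the amount of RNA, and a loss of type II cell expression after Cebpa deletion that would itself narrow the range all remain open.

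Other splits of the arrays were counted for each comparison except the interactions. For the interactions the genotype labels were kept. Residuals of a model with time and genotype but no interaction were shuffled within each time and added back to its fitted values. For the 24 h interaction 1 of 100 arrangements, the real one, gave as many genes, 2859 against 2349 for the highest shuffle. That is the smallest share 100 arrangements can give, and it takes the residuals of arrays within a time as exchangeable. Chance is unlikely by this test but not excluded, since 2349 shows a strong structure among the arrays and 1 gene passed with the range covariate. For the average over times 8 of 100 splits gave at least the real 3366 genes, the highest other gave 6966, and chance cannot be excluded. Across the 99 other splits the number of genes called rose with the difference in mean array range that a split made (Pearson r = 0.67, Spearman rho = 0.45), a difference of 0.15 for the real split and of 0.22 for the one with the most genes. For the 2 h interaction all 100 arrangements gave at least the real 0 genes, and the highest shuffle gave 6.

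The remaining comparisons allow only 10 splits, too few for a share under 0.05, and in each of them 1 split, the real one, reached its count. By genotype the real count and the highest other were 171 and 2 at 0 h, 280 and 1 at 2 h, and 10110 and 0 at 24 h. Against 0 h they were 13979 and 0 for controls at 2 h, 11939 and 0 for controls at 24 h, 12586 and 1 for Cebpa-deleted cells at 2 h, and 15468 and 0 for Cebpa-deleted cells at 24 h. From 2 to 24 h they were 2480 and 0 for controls, and 6254 and 4243 for Cebpa-deleted cells.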

How the results depend on the processing

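The alternatives with the array range as a covariate, without the 2 narrowest arrays, without 24 h, and with the trend on the level removed, the 24 h against 2 h comparisons, and the list tests under quantile normalization and median centring were chosen only after the results were seen. Of the values that answer a comparison, 351 stayed within their limits under an alternative, 136 moved and 2 lost their call; of the values of single genes and lists, 4501 stayed, 946 lost their call, 1 gained it and 25 reversed. The cause was not tested except where named. Centring each array on its median, the mean of all features of a gene, every feature tested alone and eBayes with trend and robust settings moved no count by 1.5 times.

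With the array range as a covariate, genotype gave 274 genes at 0 h, 999 at 2 h, 4 at 24 h and 796 on average, and Cebpa at 24 h was -1.30 (adjusted p = 0.138). Against 0 h it gave 940 and 3369 genes in controls and 1195 and 39 in Cebpa-deleted cells at 2 and 24 h, from 2 to 24 h it gave 115 in Cebpa-deleted cells, and 1 gene for the 24 h interaction. The lists called were 8 by genotype at 24 h, 6 and 4 in controls and 1 and 7 in Cebpa-deleted cells against 0 h, 12 and 10 for the 2 h and 24 h interactions, and 10 from 2 to 24 h in Cebpa-deleted cells. Calls shared between times were 130, 0 and 2. Reversed by genotype at 24 h were Prdx3 (0.05), H2-Ab1 (0.39), Tkt (0.11), oxidative phosphorylation (0.06), and, by the sign of their test, fatty acid oxidation (median 0) and antioxidant enzymes (-0.05). On average fatty acid oxidation (0.01) and oxidative phosphorylation (0.01) reversed. In controls from 0 to 2 h type II cell genes (0.16), cholesterol synthesis (0.47, called higher) and oxidative phosphorylation (0.06) reversed. In Cebpa-deleted cells Alkal1 at 2 h (0.86) and 24 h (1.82) and cholesterol synthesis at 2 h (0) did. Fatty acid synthesis reversed in the 24 h interaction (0.05) and from 2 to 24 h in Cebpa-deleted cells (0.05), as did cholesterol synthesis (0.24), antioxidant enzymes (0.04) and oxidative phosphorylation (0.07) in the latter.

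A second quantile normalization gave 8 genes at 0 h and 6697 at 24 h by genotype, 8361 in controls and 7730 in Cebpa-deleted cells from 0 to 2 h, and 1213 for the 24 h interaction. It called 1 list in controls at 2 h and 2 at 24 h, 5 and 10 in Cebpa-deleted cells, 7 for the 2 h interaction and 7 from 2 to 24 h in Cebpa-deleted cells. By genotype at 24 h NRF2 targets (0.18) and immediate early genes (0.08) reversed, as did transitional epithelial genes from 0 to 24 h in Cebpa-deleted cells (0.34) and, by the sign of their test, in the 24 h interaction (-0.05). With the trend on the level also removed, 6624 genes were called at 24 h.

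Without the 2 narrowest Cebpa-deleted 24 h arrays, which leaves 1 array assumed to vary like the others, 217 genes passed by genotype at 24 h, 1063 on average, 0 in the 24 h interaction and 64 from 2 to 24 h in Cebpa-deleted cells, where 3 lists were called and cholesterol synthesis (-0.06, by the sign of its test) and glucocorticoid targets (0.07) reversed. Without 24 h the average gave 591 genes.

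With only the arrays of the groups compared, 1 gene passed at 2 h, where Cebpa was -1.10 (adjusted p = 0.173), 4441 in the 24 h interaction and 1830 from 2 to 24 h in Cebpa-deleted cells, and the overlaps with 2 h were 0 and 1. Fewer arrays estimate the spread in this setting, yet the counts at 0 and 24 h, refitted alike, changed by no more than 1.5 times. At 2 h the Cebpa-deleted arrays varied more than controls in Cebpa (SD 0.52 against 0.14) and Cdh5 (0.69 against 0.23). Pon1 did not (0.27 against 0.32). The fit of all arrays pools this spread with that of the other groups.

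The replicate number as a block gave 62 genes at 2 h, 1924 on average, 775 in the 24 h interaction and 4101 from 2 to 24 h in Cebpa-deleted cells. The block has no pairing behind it: differences of arrays with the same number correlated across genes with r of -0.04, 0 and 0.04 at 0 h, -0.24 and -0.22 at 2 h, and 0.05 and 0.06 at 24 h.

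A change of at least 1.5-fold lowers counts by construction, to 2579 at 24 h and 338 on average by genotype, 6616 and 4903 in controls and 5183 and 9796 in Cebpa-deleted cells against 0 h, 1758 in the 24 h interaction, and 744 and 1470 from 2 to 24 h in controls and Cebpa-deleted cells. With an unadjusted p below 0.01 the overlaps were 264, 275 and 342. The upper 60 percent of genes by level, which tests fewer genes, gave 8433 and 7452 in controls and 7870 and 9418 in Cebpa-deleted cells against 0 h, with 4 lists in controls at 2 h, 4 at 24 h, and 2 from 2 to 24 h in Cebpa-deleted cells.

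With an estimated correlation 0 lists were called in any comparison. With fry, which does not compare a list with other genes, 0 were called at 0 h and 2 at 2 h by genotype, 27 and 19 in controls and 24 and 28 in Cebpa-deleted cells against 0 h, 0 in the 2 h interaction and 2 from 2 to 24 h in controls.

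Leaving out each array in turn gave 32 to 139 genes at 0 h, 25 to 729 at 2 h, 6128 to 10988 at 24 h and 2163 to 5783 on average by genotype, and 1 to 6, 7 to 17, 17 to 20 and 13 to 19 lists. Cebpa ranged from -0.48 to -0.37, from -1.38 to -0.88, from -1.94 to -1.74 and from -1.21 to -1.05, called at 2 h, at 24 h and on average in every fit. The 2 h interaction gave 0 to 1 genes and 0 to 12 lists, and the 24 h interaction 278 to 5828 genes and 15 to 18 lists. From 2 to 24 h it gave 1398 to 2143 genes and 4 to 10 lists in controls, and 2922 to 8093 genes and 9 to 20 lists in Cebpa-deleted cells. Counts against 0 h stayed within 10471 to 15502 genes and 11 to 18 lists.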

Other observations

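The Cebpa-deleted arrays at 2 h differed among themselves in Cebpa, in marker lists and in range. The SD of Cebpa was 0.52 on them, the largest of the 6 groups, with levels of 9.98, 8.96 and 9.31 for replicates 2, 3 and 4. On the array of replicate 2, which had the highest Cebpa of these 3, the marker lists of other cells had their lowest means. Endothelial markers averaged 8.51 on it against 9.26 and 9.36 on the other two, macrophage markers 7.31 against 7.93 and 7.86, fibroblast and smooth muscle markers 7.38 against 8.03 and 7.96, and ciliated cell markers, not called by genotype at 2 h, 7.85 against 8.33 and 8.31. Type II cell genes averaged 12.06 on it against 11.77 and 11.53. Its interquartile range was also the widest of the 3, at 2.55 against 2.355 and 2.156, so its lower marker means were not separated from its range. Without this array 729 genes differed by genotype at 2 h, in place of 280, and Cebpa differed by -1.38.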
